A study of Mus musculus with 6 samples.

How the data were processed

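Whole embryos and placentas of mice at embryonic day 12.5 were dissected, combined by tissue within each of 3 litters and snap frozen, and total RNA was extracted with TRIZOL, per the labels' protocols. Linearly amplified cRNA targets carrying Cy3 or Cy5 were prepared from the RNA. Each litter's embryo pool and placenta pool were hybridised together on 2 two-colour arrays, once with embryo in Cy3 and placenta in Cy5 and once with the dyes exchanged, which makes 6 arrays. The labels give 5 pooled for litters 1 and 2 and 3 pooled for litter 3. The array carries oligonucleotides of 60 nucleotides synthesised in place.

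Per the submitters' processing notes the arrays were processed with Agilent Feature Extraction. Its version, background correction and dye normalization are not given in the sources used here. The deposited table gives 1 value per feature and array for 22575 features, with no missing value. Neither the scale nor the direction of the values is stated. They were taken as the log10 ratio of Cy5 over Cy3, deposited by the authors as that program's standard log ratio. This rests on the limits of the scale at exactly -2 and 2, which are 100-fold on a log10 scale, on array medians between -0.00534 and 0.0108, and on opposite signs between the dye orientations. The direction was also set against 2 gene lists written down before the data were examined, the placental prolactin family and neural tissue, which came out higher in placenta and in embryo. If the true direction were Cy3 over Cy5, each sign below would turn. Values at exactly 0 or at a limit occurred on at least 1 array for 745 features. Scanner intensities were not used here, so signal over background is unknown, and the number of arrays limits the precision.

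Features were named through the platform annotation, with gene numbers set against the RefSeq table of assembly GRCm38.p6. Of the 22575 features, 4262 list 1 gene symbol, 6822 list several and 11491 list none here. A gene number was found in the RefSeq table for 4247 of the 4262 features, was not found for 15, and changed no symbol. A feature with several symbols was never used to name a gene. Features sharing a single symbol were averaged, which gave 3089 genes, of which 867 had more than 1 feature, and each other feature was kept as its own row, for 21402 rows in all. Control features were planned to be left out but are not marked in the table used here, so they remain among the features without a symbol. No genomic positions are printed, because no build is named for the array.

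Log10 ratios were multiplied by 3.3219 to give log2 ratios, and the arrays with embryo in Cy5 were turned in sign so that each value is placenta over embryo. The 2 arrays of a litter share their RNA pools, so their mean was 1 replicate and n is 3 litters. The mean over litters was tested against 0 with limma (lmFit and eBayes, two-sided, 2 residual and 1.71 prior degrees of freedom) and Benjamini-Hochberg adjustment over all 21402 rows, with a threshold of adjusted p 0.05. Large differences also had to reach 2-fold. The dye effect was tested in the same way on the mean of the unturned ratios of each litter, in which the tissue part cancels. Litter differences were tested with limma's F-test on the 6 arrays with the dye orientation as a covariate. Its spread is that of dye-swapped arrays and therefore technical. Agreement of arrays was described by correlations across rows, which are not independent replicates, so no p is given.

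Before the data were examined, 24 gene lists, the tests, the alternatives and the rule for naming genes were fixed. The rule takes the 10 genes with the largest difference in each direction among those past the threshold with the same sign on all 6 arrays. From each list it takes up to 3 members with the largest differences past the threshold and the largest member that did not pass. For the dye effect and the litter differences it takes the 3 genes with the smallest p. Lists of at least 3 measured genes were tested with limma's camera (preset correlation 0.01), with an estimated correlation and limma's fry as alternatives, and Benjamini-Hochberg adjustment over the lists. Because 6822 features list several symbols, each list was also tested over features listing any member, an alternative chosen after seeing the data.

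Alternatives fixed beforehand were centring, scaling and quantile normalization of the arrays, features as rows, leaving out exact zeros, other fits of the 6 arrays, 1 dye orientation at a time, robust eBayes and leaving out each litter. Scaling to the same spread used the median absolute value. Chosen after seeing the data were filters on features at a limit, on features without a symbol and on the outermost features of the grid, reading the values as log2, a dye term with litter as a block, and the list test on the blocked fit. The pairing of arrays by number comes from the labels, since arrays with the same number hold the pools of 1 litter. Deviations from the mean of the dye orientation correlated at -0.0167 for litter 3, -0.0998 for litter 1 and -0.0759 for litter 2 (Pearson's r across rows), and at 0.245, 0.140 and 0.263 by Spearman's rho. Arrays with different numbers gave -0.0920 to 0.108 by r and -0.289 to 0.0333 by rho. Arrays with the same number thus stood higher by rho and not by r.

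The scripts were tested on simulated litter values with the measured spreads. For placenta against embryo over 21402 rows, with 200 rows changed, 0% of changes of 0.5 log2, 26.9% of changes of 1 and 60.6% of changes of 2 were recovered, with 1 false call. With the measured differences of the 7221 called rows put in, 89.6% were recovered and 3.98% of calls were false. Those rows had been chosen by this same test, so this recovery is not its power for differences in general. For the dye effect, 60.0% of 200 rows changed by 1 were recovered with 4 false calls, and for the list tests 5 of 5 shifted lists with 0 false calls. R 4.3.3, limma 3.58.1, statmod 1.5.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.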

Results

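RNA from mouse placentas and whole embryos at embryonic day 12.5 was compared on 6 two-colour arrays with 22575 features. Tissues were pooled within 3 litters, with 5 pooled in litters 1 and 2 and 3 pooled in litter 3, and each litter was measured on a pair of arrays with exchanged dyes. There were thus 3 arrays with embryo in Cy3 and placenta in Cy5 and 3 with the opposite labelling. The deposited log10 ratios had medians of 0.00531, 0 and 0.0108 on the arrays of litters 1, 2 and 3 with embryo in Cy3, and of -0.00114, 0 and -0.00534 on those with placenta in Cy3. Between 96 and 336 features per array were at exactly 0. The study used dye swaps to judge how exact and repeatable the array was, and the ratio it measured on every array was that of placenta and embryo.

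The comparison of placenta and embryo asks which transcripts were more abundant in either tissue. All signed values are log2 ratios of placenta over embryo, given as the mean ± SD of n = 3 litters. Scale and direction are not stated with the data, how the arrays were centred is unknown, and the direction was taken from the Cy5 over Cy3 convention of the scanner software and from preset placental and neural gene lists. Among genes with a feature of their own, the highest in placenta was S100a6, which encodes a calcium-binding protein, at 5.32 ± 0.17 or 39.9-fold (adjusted p = 0.00242). Tmem37, at 4.75 ± 0.32 or 26.9-fold, and Inhbb, the subunit of activin B, at 4.68 ± 0.25 or 25.6-fold, came next. Exoc3l4 (4.02 ± 0.32), the plasma membrane calcium pump gene Atp2b3 (3.85 ± 0.24), 4930486L24Rik (3.80 ± 0.22) and Cd9, which encodes a tetraspanin (3.71 ± 0.11), were also among the 10 highest. The remaining ones were C030023E24Rik (3.59 ± 0.43), Tdrp (3.58 ± 0.43) and Myo19, a myosin of mitochondria (3.54 ± 0.33).

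At the other end, the lowest of these genes in placenta relative to embryo was Vsnl1, a neuronal calcium sensor gene, at -4.55 ± 0.17 or 23.5-fold lower (adjusted p = 0.00242). It was followed by Gpm6a, a neuronal membrane glycoprotein gene, at -4.05 ± 0.71, and Dcx, whose product binds microtubules in migrating neurons, at -3.99 ± 0.64. Igfbp5 was at -3.85 ± 0.27, Nrep at -3.73 ± 0.17 and Wars2, the mitochondrial tryptophanyl-tRNA synthetase gene, at -3.64 ± 0.65. The glutamate transporter gene Slc1a3 (-3.25 ± 0.53), D430019H16Rik (-3.22 ± 0.32), the neuronal transcription factor gene Myt1l (-3.17 ± 0.88) and Gm26787 (-3.08 ± 0.48) completed the 10 lowest. Each of these 20 genes had the same sign on all 6 arrays, and their adjusted p lay between 0.00242 and 0.0114.

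**Figure D1:**
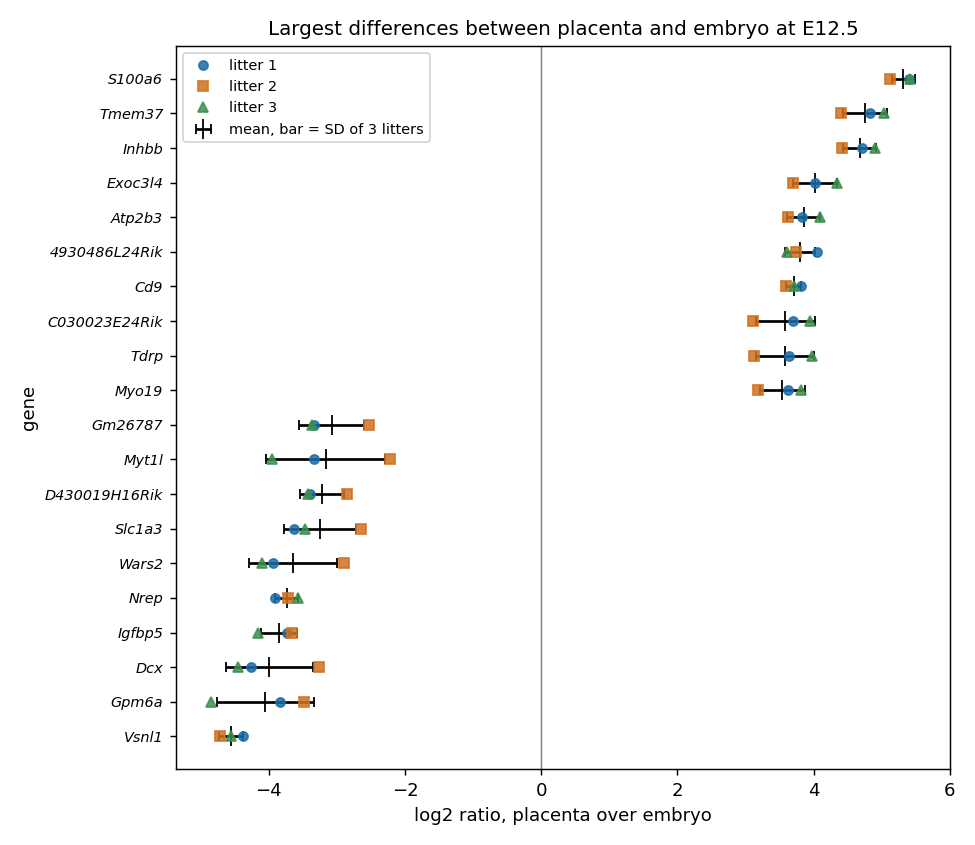
The 10 genes highest and the 10 lowest in placenta among genes with a feature of their own and the same sign on all 6 arrays, with the log2 ratio of placenta over embryo on the x axis, 1 symbol per litter, and a vertical tick with a bar for the mean ± SD of 3 litters. S100a6 is highest at 5.32 and Vsnl1 lowest at -4.55, and litters 1, 2 and 3 lie on the same side of 0 for each gene.

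In all, 7221 of 21402 genes and unnamed features (33.7%) passed limma's test, 3553 higher and 3668 lower in placenta. Of the 7221, 95.8% had the same sign on all 6 arrays. Differences of at least 2-fold were found for 2409, of which 1149 were higher and 1260 lower. Among the 3089 genes with a symbol of their own, 674 were higher and 787 lower, and 513 of these differed at least 2-fold. Features listing several symbols passed in 3396 of 6822 cases and features without a symbol in 2364 of 11491. These counts depended on each litter. They were 2719 without litter 1, 4457 without litter 2 and 0 without litter 3, where the smallest adjusted p was 0.0520. Fewer litters also give less power. Without litters 1, 2 and 3 in turn, limma's unadjusted p was under 0.05 for 7349, 8356 and 7645. Its adjusted p was under 0.1 for 5455, 7247 and 5512. The fall to 0 without litter 3 is thus a matter of where the threshold lies. All 7221 kept their direction in each case. Their selection by the test on all litters fixes this, since a mean that changes sign without 1 litter would not have passed. The p-values rest on the 3 litters as separate pools, and turning the litters against each other in the 4 possible ways cannot give a share under 0.25. Of the genes named above, Myt1l lost its call without litter 1 (-3.09, adjusted p = 0.0541), and all 20 lost it without litter 3.

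Markers of the embryo's own tissues were examined next. Of 14 neural genes with a feature of their own, 12 were lower in placenta, 0 were higher and 2 did not pass (median -1.79, camera adjusted p = 1.2e-05). With an estimated correlation the adjusted p of the list was 0.582. That correlation is estimated from only 2 residual degrees of freedom. Such a p-value therefore cannot decide on a list's call, here or below. The neural list and the placental prolactin family had also served to settle the direction of the ratios. Here and below, the signs of these lists are therefore not separate results. Beside Gpm6a and Dcx, the axon growth gene Dpysl3 was at -2.84 ± 0.27. The transcription factor gene Pax6 had the largest difference that did not pass, -2.98 ± 3.33, with values of its feature at the limit of the scale or at 0. Of 6 cartilage and bone genes, 4 were lower and 2 did not pass (median -1.31, camera adjusted p = 0.00569, and adjusted p = 0.582 with an estimated correlation). Sox6, a chondrocyte transcription factor gene, was at -2.39 ± 0.54, the mesenchymal gene Twist1 at -1.97 ± 0.40 and the collagen gene Col9a3 at -1.46 ± 0.37. Sox5, at -1.02 ± 0.57, missed the threshold (adjusted p = 0.0503) and passed with the 6 arrays blocked by litter (adjusted p = 0.0152), and without litter 2 (-1.32, adjusted p = 0.0265). It also passed with arrays centred (0.0460) or scaled (0.0251) and with each feature as its own row (0.0483). Here and below, the litter block had a consensus correlation of 0.0400, so it treated the 6 arrays almost as independent. Its p-values therefore do not rest on n = 3 litters and rescue no call. Adjusted over the list alone, 12 neural and 6 cartilage and bone genes were lower.

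Over genes with a feature of their own, none of the tested lists for muscle and other embryonic tissues passed camera. The heart list had 2 of 5 genes lower, the cardiac myosin light chain gene Myl2 at -1.85 ± 0.36 and the calcium release channel gene Ryr2 at -0.74 ± 0.33, and Hspb7 at -0.24 ± 0.07 did not pass (adjusted p = 0.0617, 0.00997 with the litter block and 0.0472 with arrays scaled). Of 3 skeletal muscle genes, Tnnt3 was lower at -0.90 ± 0.38 and 2 did not pass, with Actc1 at -0.34 ± 0.26 (adjusted p = 0.123, 0.0426 with the litter block). Of 4 Hox genes, Hoxc8 (-0.57 ± 0.17) and Hoxb4 (-0.46 ± 0.20) were lower, while Hoxc4, at -1.25 ± 1.13, did not pass. Of 3 epidermal genes, Tfap2b (-1.09 ± 0.45) and Sfn (-0.42 ± 0.09) were lower, and Tfap2a was at 0.14 ± 0.16 and did not pass. The 3 features of Tfap2b ranged from -1.91 to -0.61, and 1 of them passed. Maf, the 1 measured gene of the eye and pigment list, was lower at -1.51 ± 0.27. Camera's adjusted p was 0.232 for the heart list, 0.216 for skeletal muscle, 0.264 for Hox genes and 0.340 for epidermis. By limma's fry, which does not compare a list with other genes, the adjusted p was 0.0299 for heart, 0.0284 for Hox genes, 0.0257 for epidermis and 0.0948 for skeletal muscle. Adjusted over the list alone, 3 heart genes were lower and the counts of the other lists in this paragraph were the same. Without litter 1, the calls of Ryr2 (adjusted p = 0.113), Tnnt3 (0.114), Hoxc8 (0.0745), Hoxb4 (0.133), Sfn (0.108) and Tfap2b (0.0942) ended. Without litter 2, those of Hoxc8 (0.0683), Hoxb4 (0.137) and Sfn (0.0670) did. With only the arrays with embryo in Cy3, the calls of Ryr2 (0.106), Hoxb4 (0.0971) and Tfap2b (0.0533) ended, and with only those with placenta in Cy3 that of Ryr2 (0.114).

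Groups of genes with known roles in the placenta were examined as well. Of 6 nutrient transporter genes, 4 were higher in placenta and 2 did not pass (median 1.5015, camera adjusted p = 0.0389, and adjusted p = 0.582 with an estimated correlation). The glucose transporter gene Slc2a1 was at 2.66 ± 0.12, the transferrin receptor gene Tfrc at 2.11 ± 0.28 and the monocarboxylate transporter gene Slc16a3 at 1.52 ± 0.19. Slc2a3, another glucose transporter gene, was at -0.08 ± 0.07 and did not pass. The list's call ended without litter 2 (median 1.57, adjusted p = 0.0684) and with arrays scaled to the same spread (median 1.51, adjusted p = 0.0881). Prl7c1, the 1 gene of the placental prolactin family with a feature of its own, was higher at 2.37 ± 0.37, a sign already used to settle the direction. Of 2 epithelial keratin and junction genes, the E-cadherin gene Cdh1 was higher at 2.28 ± 0.23, and Ocln, at 0.38 ± 0.36, did not pass. Of 2 steroid synthesis genes, Cyp11a1, whose enzyme starts steroid synthesis from cholesterol, was higher at 0.88 ± 0.14, and Fdx1 was at -0.23 ± 0.08 (adjusted p = 0.0720, 0.00760 with the litter block). Among 5 trophoblast regulators and markers, Flt1, a receptor for vascular endothelial growth factor, was higher at 3.05 ± 0.52. The other 4 did not pass, with Ascl2 at -0.82 ± 0.48 (adjusted p = 0.0564, 0.00589 with the litter block and 0.0479 with arrays centred on their median). That list had a median of -0.19, a mean of 0.38 and a camera adjusted p of 0.767. Adjusted over the list alone, 2 trophoblast genes and 1 steroid synthesis gene were lower, and the counts of higher genes were the same for each list in this paragraph.

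Most features of the placental families list several symbols and name no single gene. Over features listing any member, 5 of 6 features of the prolactin family were higher, with the largest ratio at the upper limit of the scale, so at least 100-fold (camera adjusted p = 0.000242, and 0.499 with an estimated correlation). Of 15 keratin and junction features, 12 were higher and 2 lower (adjusted p = 3.92e-05, 0.499 with the estimate), and of 25 nutrient transport features 16 were higher and 0 lower (adjusted p = 1.04e-05, 0.499 with the estimate). Higher features numbered 17 of 35 for trophoblast markers (2 lower, adjusted p = 0.00156), 7 of 9 for steroid synthesis (adjusted p = 0.0105) and 10 of 19 for endothelium (adjusted p = 0.00295). With an estimated correlation the adjusted p was 0.499 for each of these 3. Such features can also list genes outside the list. Of rows listing only members, 1 of 5 was higher for trophoblast markers (median -0.19), 1 of 2 for steroid synthesis and 3 of 5 for endothelium. It was 3 of 3 for the prolactin family, 3 of 4 for keratins and junctions and 6 of 8 for nutrient transport. Of 14 rows listing only neural genes, 12 were lower and 0 higher. Lower features listing any member numbered 27 of 52 for neural tissue with 8 higher (adjusted p = 0.000181), 9 of 20 for cartilage and bone with 2 higher (0.00309) and 7 of 14 for heart with 1 higher (0.00619), each at 0.499 with an estimated correlation. They numbered 9 of 18 for skeletal muscle with 4 higher (0.0199), 9 of 15 for Hox genes (0.00159) and 26 of 45 for the cell cycle with 6 higher (1.04e-05), at 0.499, 0.499 and 0.503 with an estimated correlation. The placental cathepsins had 1 higher and 3 lower of 8 features (adjusted p = 0.620), with values from -1.11 to 6.01. Of the 5 that list only cathepsin members, 1 was higher and 0 were lower (median 0.40). The 3 lower ones thus also list genes outside the family. The pregnancy-specific glycoproteins had 1 higher and 1 lower of 2 features. None of these lists passed with an estimated correlation, which with 3 litters does not decide on their calls.

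Markers of other cells that a placental dissection can hold went both ways. Of 5 leukocyte and uterine natural killer cell genes, the macrophage receptor gene Csf1r (2.18 ± 0.46) and the interleukin receptor gene Il2rb (2.16 ± 0.21) were higher. S100a9, a gene of neutrophils, was lower at -1.58 ± 0.29, and 2 did not pass, among them Ptprc at 0.12 ± 0.12, which passed with only the arrays with embryo in Cy3 (0.54, adjusted p = 0.0257). Camera's adjusted p for that list was 0.351 and fry's was 0.0259. Of 4 endothelial genes, Sox17 (0.88 ± 0.14) and Pecam1 (0.80 ± 0.22) were higher and 2 did not pass, with Esam at 0.34 ± 0.24 (adjusted p = 0.0986, 0.0448 with the litter block). The endothelial list had a camera adjusted p of 0.216. Of 4 decidual genes, Fst, which encodes the activin-binding protein follistatin, was higher at 1.41 ± 0.29. The other 3 did not pass, with Timp3 at -0.25 ± 0.17 (adjusted p = 0.118, 0.0255 with the litter block), and the list had a median of -0.13, a mean of 0.22 and a camera adjusted p of 0.978. Over 16 features listing any decidual gene, 7 were higher and 3 lower (camera adjusted p = 0.655). Their median was -0.07, their mean 1.01 and their largest value 6.26. Of 5 rows listing only decidual genes, 2 were higher and 0 lower. Of 2 erythroid genes, the carbonic anhydrase gene Car2 was higher at 2.62 ± 0.17 and the membrane skeleton gene Add2 lower at -1.999 ± 0.37. None of 3 hepatocyte and yolk sac endoderm genes passed, and Trf, the transferrin gene, had the largest difference at 1.05 ± 0.86 (adjusted p = 0.108, 0.0210 with the litter block). That list's camera adjusted p was 0.978. Adjusted over the list alone, the counts of genes with a feature of their own were the same for these lists. The call of Pecam1 ended without litter 1 (adjusted p = 0.0733) and with only the arrays with placenta in Cy3 (0.0537).

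Imprinted genes, which are expressed from 1 parental allele, were split. Of 8 measured, 3 were higher, 2 lower and 3 did not pass (camera adjusted p = 0.767, fry adjusted p = 0.0284). Grb10, a growth-restraining adaptor gene, was at -2.28 ± 0.09, Sfmbt2 at 1.95 ± 0.37 and Gatm, an enzyme of creatine synthesis, at 1.49 ± 0.22. Of 12 cell cycle genes, 5 were lower, 1 was higher and 6 did not pass (median -0.36, camera adjusted p = 0.0853). The cyclin D2 gene Ccnd2 was at -2.06 ± 0.88, its kinase partner Cdk4 at -1.18 ± 0.17 and Cdc20 at -0.97 ± 0.20. Aurka, at -0.42 ± 0.32, did not pass (adjusted p = 0.107, 0.0384 with the litter block). Without litter 1 the cell cycle list passed (median -0.44, adjusted p = 0.0287), whereas with an estimated correlation over all litters its adjusted p was 0.582. Of 10 hypoxia and glycolysis genes, 5 were higher, 2 lower and 3 did not pass (camera adjusted p = 0.216, fry adjusted p = 0.00520). Beside Slc2a1, the phosphofructokinase gene Pfkp was higher at 2.19 ± 0.07, whereas the lactate dehydrogenase gene Ldha was lower at -1.79 ± 0.54. Vegfa did not pass at 0.08 ± 0.21, but its 2 features passed in opposite directions, at -1.04 and 1.20. Among 867 genes with more than 1 feature, 41 had features past the threshold in both directions. Of 4 extracellular protease and inhibitor genes, the plasminogen activator gene Plat was higher at 0.90 ± 0.22, Timp2 was lower at -0.57 ± 0.16 and 2 did not pass (adjusted p = 0.653). The 3 features of Timp2 ranged from -1.27 to -0.07, and 1 passed. Of 7 housekeeping references, 3 were higher, 1 lower and 3 did not pass (adjusted p = 0.332). Beside Tfrc, Ppia was at 0.64 ± 0.15 and Rplp0 at -0.52 ± 0.20, and Gusb, at 0.26 ± 0.26, did not pass. Adjusted over the list alone, 4 imprinted genes were lower and the counts of the other lists in this paragraph were the same. Without litter 1, the calls of Ldha (adjusted p = 0.0501), Plat (0.0577), Timp2 (0.0820), Ppia (0.0603) and Rplp0 (0.0932) ended. Without litter 2, those of Timp2 (0.0561), Ppia (0.0520) and Rplp0 (0.0719) did. With only the arrays with embryo in Cy3 the call of Ldha ended (0.0532), and with only those with placenta in Cy3 those of Ccnd2 (0.0954) and Rplp0 (0.0723). Of the 2 features of Rplp0, 1 passed.

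**Figure D2:**
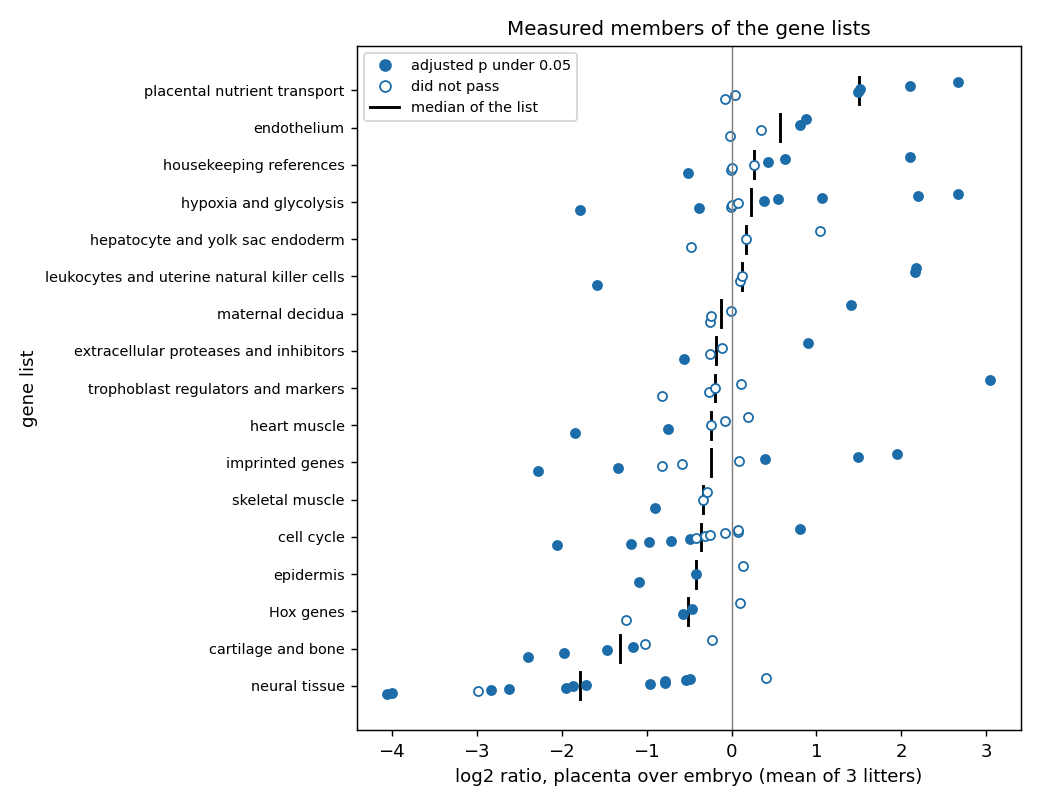
Members of the 17 tested gene lists, with the log2 ratio of placenta over embryo (mean of 3 litters) on the x axis and 1 line per list. Filled circles passed limma's test, open circles did not, and black ticks are list medians, from -1.79 for neural tissue to 1.5015 for placental nutrient transport.

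The dye effect asks how far a ratio depended on which dye carried which tissue, as part of the study's aim of measuring accuracy. No gene or feature passed limma's test (0 of 21402, smallest adjusted p = 0.292), while 3311 (15.5%) had an unadjusted p under 0.05. The genes with the smallest p were Adar, an RNA-editing enzyme gene, whose Cy5 over Cy3 part was 0.49 ± 0.02 log2, Mfhas1 at -0.39 ± 0.02 and BC034090 at -0.45 ± 0.08 (SD, n = 3 litters, adjusted p = 0.292 for each). The median absolute dye part was 0.0881 log2, against a median absolute difference between the tissues of 0.258. Its 95th percentile was 0.679 log2. The simulated dye changes were of 1 log2, so how many dye parts of the sizes seen here the test would find is unknown. In 25.3% of genes and features the dye part was larger than the difference between the tissues. A fit of the 6 arrays with litter as a block gave 1 feature, which has no symbol here (-0.81 log2, adjusted p = 0.0275), and 4207 with an unadjusted p under 0.05.

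The agreement of dye-swapped arrays describes the precision of the array. Across all genes and features, the turned ratios of the pair of arrays of a litter correlated with a Pearson's r of 0.288 in litter 1, 0.811 in litter 2 and 0.485 in litter 3. The corresponding Spearman's rho was 0.554, 0.615 and 0.680. Arrays of different litters with the same dye orientation had a median r of 0.660 and rho of 0.769, and those of different litters and orientations 0.545 and 0.603. These values depended on which features were counted. Among the 9911 genes and features that list a gene symbol, dye-swapped arrays had a median r of 0.916 and rho of 0.848, against 0.883 and 0.880 for the same orientation in other litters and 0.857 and 0.833 for other orientations in other litters. Among 10855 features without a symbol, leaving out the outermost positions of the array, the rho was 0.414 between dye-swapped arrays and 0.635 between litters in the same orientation. The SD of the difference between dye-swapped arrays was 0.482 log2 where a symbol was listed and 0.801 where none was, and without intensities it is unknown whether the latter features were dim. A set of 636 features on the outermost positions, none with a symbol, held many values far from the diagonal, and without it the median r of dye-swapped arrays was 0.770.

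**Figure D3:**
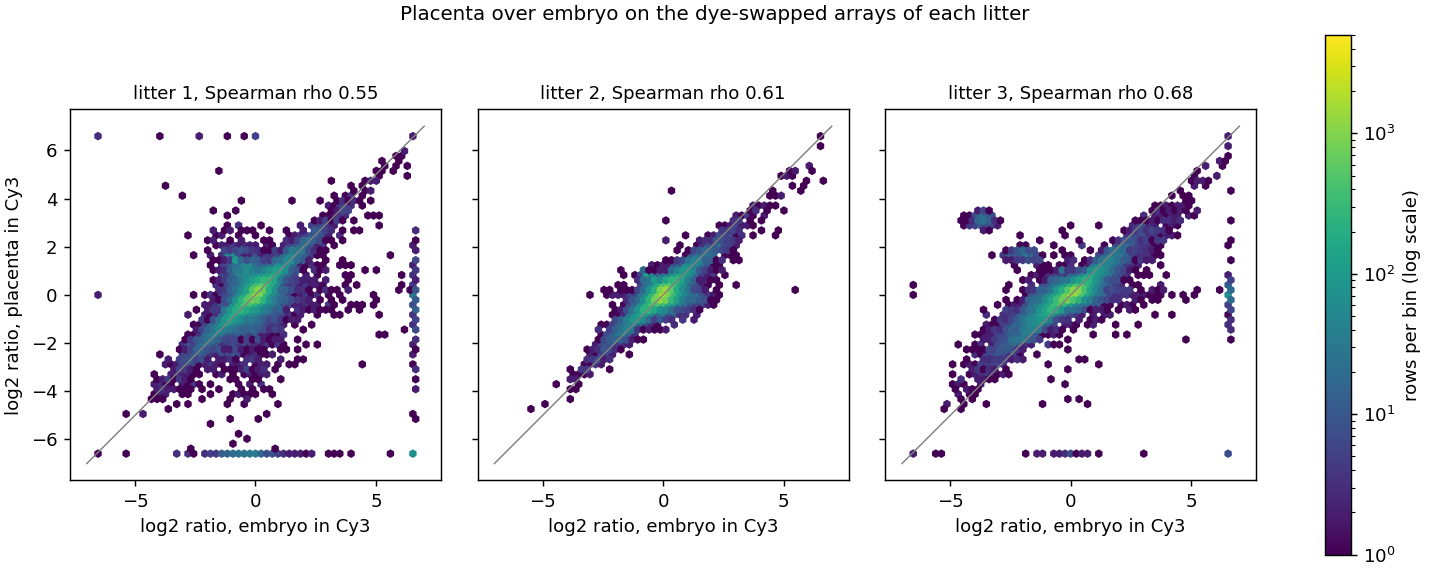
Log2 ratio of placenta over embryo on the array with embryo in Cy3 (x axis) against the array with placenta in Cy3 (y axis) for each litter, with all 21402 genes and features binned and the colour giving the number per bin on a log scale. Rho is 0.55, 0.61 and 0.68 in litters 1, 2 and 3. Lines of points at the borders are values at the limits of the scale, and the 2 clusters at upper left in litter 3 are features without a symbol.

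Litter differences were tested to see whether the ratio of placenta to embryo varied between litters by more than between dye-swapped arrays. None passed limma's F-test (0 of 21402, smallest adjusted p = 0.442, and 0 without the dye term), and 2408 (11.3%) had an unadjusted p under 0.05. With 3 litters and a dye term fitted to 6 arrays, few degrees of freedom remain, and the power of this test was not simulated. That none passed therefore does not show that the litters were alike. Among genes with a feature of their own, the smallest p belonged to Ttr, the transthyretin gene, with ratios of 0.83 in litter 1, 0.80 in litter 2 and -1.13 in litter 3. Trf was second, with 1.63, 1.45 and 0.06, and Adar came next, with 2.21, 0.70 and 1.28. Litter 3 also had the smaller pool. Litter 2 had smaller ratios than the others. Among genes and features that list a symbol, the SD of the ratios was 0.775 log2 in litter 2, against 0.984 in litter 1 and 0.996 in litter 3.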

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

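The filters on features at a limit, on symbols and on the outermost features, the reading as log2, the dye term with a litter block, lists over features naming any member and the blocked list test were chosen after seeing the data. With no missing values, the alternative rule for them was not run. Among alternatives for counts, correlations and numbers of lists, 100 stayed within 1.5-fold (counts) or within the SD over pairs of arrays (correlations) and 24 moved. Leaving out 1 litter gave ranges of 0 to 2066 higher and 0 to 2391 lower, and for 2-fold differences of 0 to 1220 higher and 0 to 1445 lower. Only genes with 1 symbol gave 816 higher and 958 lower, and 244 and 283 at 2-fold, since fewer were tested. Read as log2, the values gave 70 higher and 30 lower at 2-fold, by construction. The dye effect gave 1 with the litter block and 0 otherwise. Median Pearson's r moved to 0.770 for dye swaps without the outermost features, and to 0.916, 0.883 and 0.857 (dye swap, same and other orientation) with a symbol listed. Without features at a limit it was 0.818 (same orientation) and 0.697 (other orientation). Lists past the threshold numbered 0 with an estimated correlation, 9 with fry and 12 over features listing any member. The causes of these last shifts were not tested.

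Of the values of 76 named genes under 10 alternatives, 640 kept direction and call, 89 lost a call, 26 gained one and 5 reversed, none of which had passed. Reversed were Timp3 (0.0509) and Ptprc (-0.0542) in their least significant feature, Ptprc (-0.29) and Tfap2a (-0.0739) with placenta in Cy3 only, and Vegfa without litter 1 (-0.0476, to 0.1416 without litter 3). Leaving out litter 3 ended 59 calls, since no gene or feature then passed limma's test (smallest adjusted p = 0.0520). Among lists the direction of the test, with the list's median, turned for trophoblast markers with fry (-0.19) and over any member (0.44), and for proteases over any member (0.11). Decidua turned with scaled arrays (-0.11), embryo in Cy3 only (0.0633), without litter 1 (0.0292, to -0.1621 without litter 2), with fry (-0.13), over any member (-0.0734) and with the litter block (-0.13). The hepatocyte list turned without litter 1 (-0.17) and without litter 2 (-0.15), against 0.8146 without litter 3. Each of these medians over 3 genes is the value of Ttr, which was 0.83 in litter 1, 0.80 in litter 2 and -1.13 in litter 3. Beyond this, the causes of the turns were not tested.

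With litter as a random block (consensus correlation 0.0400) the 6 arrays gave 4850 higher and 4862 lower, and 7008 of the 7221 calls were shared. Taken as independent, the arrays gave 4974 higher and 4956 lower, so the block hardly allowed for the shared pools of a litter. Except for the genes given with their blocked p, the block changed no call of a list or of the 76 genes named by the fixed rule, and it was not examined for the genes named outside the rule. No intensities were used, so what signal over background limits is unknown.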

Other observations

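The tests on litter 2, on Ttr and Trf, on features without a symbol and on the outermost features were chosen after their results were seen, as were the genes named in this part outside the fixed rule. Grouping genes by the stem of their symbol gave 28 families of at least 8 genes, and 4 of them were lower in placenta by camera, whereas none passed with an estimated correlation. Of 52 zinc finger genes with the stem Zfp, 21 were lower and 4 higher (median -0.32, adjusted p = 0.000664, and 0.618 with an estimated correlation), with Zfp219 at -2.15 ± 0.20 and Zfp28 at -2.05 ± 0.41 (SD, n = 3 litters). Of 9 Trim genes, 6 were lower and 0 higher (adjusted p = 0.0160, 0.618 with the estimate), with Trim2 at -2.52 ± 0.42 and Trim59 at -1.98 ± 0.18. Of 9 genes with the stem Cdk, which takes in Cdk2ap1, 6 were lower (adjusted p = 0.0160, 0.618 with the estimate), with Cdk4 at -1.18 ± 0.17 and Cdk6 at -0.77 ± 0.26. Of 18 Ppp genes, subunits of protein phosphatases, 9 were lower (adjusted p = 0.0160, 0.618 with the estimate), with Ppp1r9a at -1.43 ± 0.09. Of these 4 families, 3 also passed without each litter in turn and Ppp reached 0.0556. Against the trend of its family, Zfp42, a gene of pluripotent and trophoblast cells, was higher at 3.36 ± 0.95. Bst2 (3.50 ± 0.41), Tgm2 (3.20 ± 0.06) and S100g (3.18 ± 0.89) were also high in placenta.

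The log2 differences of features that share a symbol had an intraclass correlation of 0.551 over 867 genes, against at most 0.0614 in 100 shuffles of the features. This is consistent with symbols that mostly name what the features detect, and the 41 genes with features past the threshold in both directions are exceptions.

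By Spearman's rho, arrays of the same dye orientation correlated better between litters than the dye-swapped arrays of 1 litter, with a gap in the median of 0.154. By Pearson's r the order turned without the outermost features, with a median of 0.770 for dye swaps against 0.727. It also turned among features that list a symbol, with 0.916 against 0.883. The rest of this paragraph concerns the gap in rho. Values at a limit or exact 0 do not account for it, since the gap was 0.160 without those features. A dye bias belonging to each feature is a candidate explanation, since the dye parts of different litters correlated with an r of at least 0.283 over all features. Without the outermost features that r was 0.242 to 0.275. The gap was 0.0317 among those that list a symbol and 0.221 among those inside the edge that list none. The dye parts correlated about as well with a symbol (0.2196 to 0.349) as without (0.236 to 0.284). Such a correlation does not give the size of the dye part relative to the ratios. The SD of the litter ratios was 0.775 to 0.996 with a symbol and 0.461 to 0.835 without. The SD of the difference between dye-swapped arrays was 0.482 against 0.801. How far this accounts for the gap was not tested. No biological explanation was tested.

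The ratios of litter 2 were smaller than those of litter 3 by a factor of 0.750 among 2329 genes and features of size 1 to 2 in litter 1, and of 0.793 among 203 of size 3 or more. A mixed dissection that affected only 1 of the pools of litter 2 would put a limit on extreme ratios, and the data pass it. Embryo RNA in the placental pool (20.8% needed) would hold ratios above -2.27, yet 7 of 7 of those under -4 in litters 1 and 3 lay below, and placental RNA in the embryo pool (12.7% needed) would hold them under 2.98, yet 24 of 25 of those over 4 lay above. One scale factor for the arrays of litter 2 could account for the pattern, as the ratios differed by 0.0429 (interval from a bootstrap over genes and features -0.0004 to 0.0916). Mixing in both pools of litter 2 and a biological difference between litters stay open and were not tested.

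Ttr and Trf were lower in litter 3 than the mean of litters 1 and 2 by -1.95 and -1.48 log2. Yolk sac or other endoderm, or decidua, carried along with the placentas of litters 1 and 2 cannot be told apart from other differences of litter 3, because it is a single litter with no spread between litters to set it against. Without Ttr and Trf, 18 features listing a hepatocyte and yolk sac gene had a median shift of -0.2554 and 14 of them were lower, and 16 features listing a decidual gene had a median shift of -0.0409. Other lists moved too, with median shifts of -0.27 for skeletal muscle, -0.2555 for the cell cycle and -0.25 for placental cathepsins. Leukocytes were at -0.15, and erythroid cells and neural tissue at -0.12. Upward shifts were 0.24 for trophoblast markers, 0.14 for nutrient transport and 0.13 for endothelium. Liver RNA in the embryo pool of litter 3, its smaller pool and a biological difference between litters stay open and untested.

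Turning the litters' ratios against each other in the 4 possible ways cannot give a share under 0.25. The real arrangement, 1 of the 4 ways, gave 7221 genes and features against at most 0 in the others, 2409 against 0 at 2-fold and 3 lists against at most 2. For the dye effect all 4 ways gave 0.

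If features are numbered line by line, the 636 features on the edge of the grid hold none with a symbol and repeat in a cycle of 4. In the first line, features of the second class had a Cy5 over Cy3 ratio of -3.71 and -3.18 log2 on the arrays of litter 3, against -0.40 and -1.14 in litter 1 and -0.36 and -0.65 in litter 2, with an SD of 0.166 or less on each array. The edge held 302 of the 740 values at the upper limit, which far outnumbered the 28 at the lower one. At the upper limit on both arrays of a litter were 79 features, 51 of them on the edge. Of the edge features, 4 passed the test of placenta against embryo, and leaving the edge out gave 3747 higher and 3908 lower.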
